A study of Mus musculus with 15 samples.

How the data were processed

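RNA was measured by sequencing in mouse embryonic fibroblasts wild type, heterozygous or knockout for Actb. Per the labels' protocols, confluent cells were moved at day 0 from DMEM to osteogenic medium with dexamethasone and forskolin, and RNA was taken at days 4 and 14 and made into libraries with an unstranded TruSeq kit. The 15 samples form 5 groups of 3: WT and KO at both days and HET at day 14. Genotype and day were read from the labels. The labels give replicate numbers and no batch, embryo or culture.

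The deposited files hold raw counts per gene, 1 file per sample. Per the submitters' processing notes, reads were aligned with TopHat2 2.1.0 to GRCm38.p4, counted with HTSeq and tested with DESeq2. The versions of HTSeq and DESeq2, the annotation release and the strand setting of the counting are not given in the sources used here. Each file lists 46603 Ensembl gene IDs. GENCODE M21, also on GRCm38, gave a symbol and coordinates to 46091 of them, and the other 512 held 0.051% of counts. No sample held a count for 13544 IDs.

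Everything below was computed from the counts. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with robust dispersion on all 15 samples, after filterByExpr on the groups and TMM scaling. It covered 15296 genes, with a common biological coefficient of variation of 8.33%, and 7 comparisons: KO against WT, HET against WT and KO against HET at day 14, KO against WT at day 4, day 14 against day 4 in WT and in KO, and the interaction of genotype and day. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The SE of a log2 fold change is the Wald SE of the fit, with the variance of a library never set below its counting error. CPM values use TMM-scaled library sizes. Where a group had no count, the fold is a bound with that group set at 3 counts. Where it had 1 to 3 counts, the ratio has a 95% counting interval. Both cover counting error only and assume that counts vary as in random sampling of reads. At 10 to 100 counts, the variance between libraries of a group was 2.06 to 2.91 times that of such sampling. The intervals may thus be too narrow and the bounds too high.

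The comparisons, the gene lists and the rule for naming genes were fixed before the data were examined. The 41 gene lists were compiled from general knowledge of bone and other cell types, the cytoskeleton, signalling pathways, metabolism, chromatin and RNA quality. Some lists share members. The smooth muscle list and the SRF and MRTF list share Acta2, Actg2, Tagln, Cnn1, Tpm1 and Myl9. Acta2 and Actg2 are also actin isoform genes, so calls of these lists are not independent. Camera (limma 3.58.1, preset correlation 0.01, on voom values) tested the 39 lists with at least 4 tested genes, adjusted over the lists of a comparison. Camera with a correlation estimated per list and fry were the alternatives. A count "adjusted over the list alone" repeats the adjustment on the members' p-values only.

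Genes are named by 4 routes. The first is all 6 actins. The second, in each pairwise comparison, is the 6 largest increases and 6 largest decreases among genes past the threshold, with a mean of at least 10 CPM in the higher group, replicates that do not overlap between groups and no predicted name. Chance separates 10% of genes in this way with 3 against 3 samples. For the interaction it is 5 in each direction. The third is up to 2 risen and 2 fallen members of each list with the smallest adjusted p. The fourth is 15 well-known genes of bone, fat, cartilage and controls.

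The alternatives tried were DESeq2 1.42.0, RLE scaling, no filter beyond 1 count, a filter of 1 CPM in 3 samples, only the samples of the groups compared, the replicate number as a block, and each replicate left out in turn. A per-library spline correction for exon length and GC content (5 degrees of freedom), the sum of HET replicates 1 and 3 as 1 library, and list tests without HET replicate 2 or WT replicate 3 of day 14 were chosen after seeing the data. The replicate numbers did not pair samples: over 30 pairs of groups with the same number, the correlation of library residuals ran from -0.606 to 0.671, with a median of -0.009 and 2 pairs above 0.1. The agreement of comparisons was set against 5 simulations without an effect.

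The pipeline was tested on simulated data. All 15 libraries were redrawn from group means and fitted dispersions, with the KO mean of day 14 set to that of WT. With 200 genes changed in KO at day 14, the pipeline recovered 90%, 98%, 100% and 100% of those changed 1.5, 2, 4 and 8-fold. It called 8 of 14801 unchanged genes. The simulated list was found with an adjusted camera p of 1.12e-77, and none of 39 other lists was called. The changed genes were few and balanced in direction, and genes were drawn independently. The simulation thus did not test the scaling under widespread change or lists of correlated genes. Counts per gene do not separate exons or alleles, so the form of the targeted allele was not examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3.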

Results

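RNA was sequenced from mouse embryonic fibroblasts that were wild type (WT), heterozygous (HET) or knockout (KO) for the beta-actin gene Actb and that had been cultured in osteogenic medium to turn them into osteoblasts. The deposited counts cover 15 libraries in 5 groups of 3: WT and KO at day 4, and WT, KO and HET at day 14. No heterozygous library of day 4 was analysed here. Reads counted in genes, in M per library, ranged from 19.9 to 47.5. They were 25.7 to 47.5 in WT and 30.7 to 35.7 in KO at day 4, and 20.02 to 20.42 in WT, 21.5 to 24.8 in KO and 19.9 to 22.2 in HET at day 14. The series asks how the transcriptomes of the reprogrammed cells differ among the 3 genotypes. Group levels below are mean CPM (counts scaled to the size of each library) ± SD of n = 3 libraries, and fold changes are log2 values ± SE. A gene placed at a value without a unit is at that log2 change in the comparison described. Mitochondrially encoded genes took 0.415% to 0.421% of counts in WT at day 4 and 0.484% to 0.542% at day 14, against 0.836% to 0.845% and 1.08% to 1.12% in KO and 0.729% to 0.851% in HET. Ribosomal protein genes took 3.15%, 3.57% and 3.94% in the WT libraries of day 14 and 2.93%, 4.21% and 2.97% in the HET libraries. The labels do not say that replicates came from separate cultures, nor how many embryos stand behind each genotype. P-values thus measure only the spread between these libraries. In WT at day 4 and in KO at both days, the chi-square per degree of freedom between 2 libraries was 2.15 to 3.09. In WT at day 14 it was 5.34 to 20.47. Between KO replicates 1 and 2 of day 14 it was 2.18 at 10 to 100 counts and 3.14 in the highest range of counts. A spread this small leaves open that libraries shared a culture, in which case p-values leave out variation between cultures.

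Actb, the targeted gene, followed the genotype labels in every library. In CPM, the WT libraries held 1193, 1186 and 1164 at day 4 and 2947, 2974 and 3067 at day 14, the HET libraries held 1488, 1642 and 1437, and the KO libraries held 129.9, 139 and 135 at day 4 and 46.5, 43.0 and 44.6 at day 14. Actb (ENSMUSG00000029580) lies on chromosome 5 at 142903115 to 142906754 of GRCm38, on the minus strand. At day 14 it was lower in KO than in WT by a log2 change of -6.07 ± 0.06 (edgeR adjusted p = 4.28e-18) and lower in HET by -0.98 ± 0.05 (edgeR adjusted p = 3.6e-10). At day 4 the KO difference was -3.14 ± 0.05 (edgeR adjusted p = 4.82e-16).

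The 3 other actins that could be tested were higher in KO than in WT at both days. Actg1, the gamma cytoplasmic actin (ENSMUSG00000062825, chromosome 11, 120345690 to 120348542), stood at 441 ± 11 and 812 ± 77.3 CPM in WT at days 4 and 14, at 2319 ± 25.1 and 2494 ± 19.2 in KO, and at 1326 ± 268 in HET. Acta2, the smooth muscle alpha-actin (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590), stood at 0.439 ± 0.133 and 25.9 ± 0.786 CPM in WT, at 2116 ± 10.1 and 489 ± 12.6 in KO, and at 75 ± 7.44 in HET. Actg2, the smooth muscle gamma-actin (ENSMUSG00000059430, chromosome 6, 83512905 to 83536265), had no count in WT at day 4 and 95.2 ± 3.28 CPM in KO, at least 3360-fold higher with WT set at the floor of 3 counts over the group. At day 14 the Actg2 ratio of KO to WT was 171 (95% counting interval 47 to 1420). Acta1 and Actc1, the skeletal and cardiac actins, had at most 11 and 4 counts over any group and were not tested. Actins are close in sequence, so their counts are uncertain wherever reads were shared, and the library kit does not mark strand, so overlapping antisense transcripts cannot be told apart for any gene here.

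**Figure D1:**
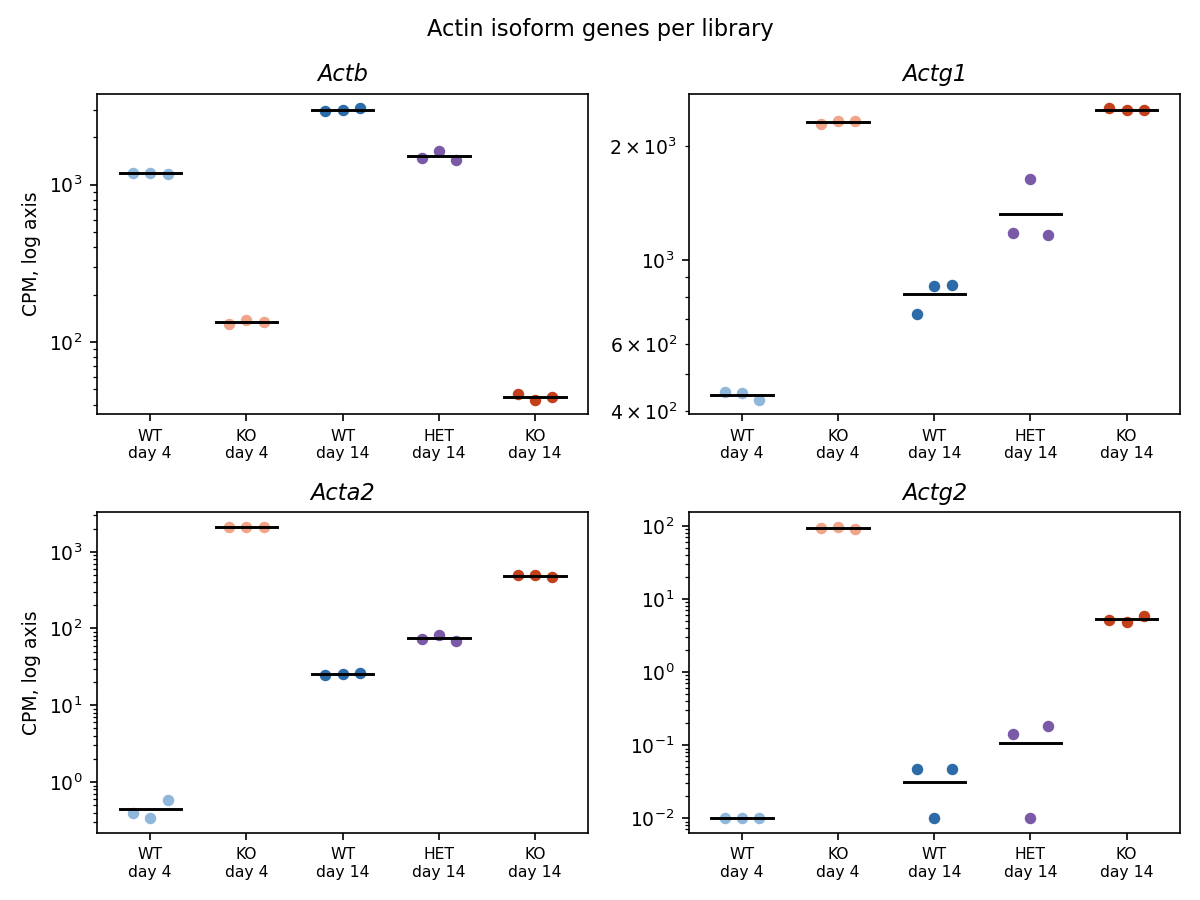
CPM of the actin genes in each library, on a log axis, with 1 point per library and a line at each group mean; a library without counts is drawn at the foot of the axis. Actb falls from 2996 CPM in WT to 44.7 CPM in KO at day 14, while Acta2 is at 25.9 CPM in WT and 489 CPM in KO.

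At day 14, KO cells had higher interferon response genes than WT, while the genes of the osteoblast program went both ways. Smooth muscle, adipocyte and Wnt pathway genes also passed as lists, but not with an estimated correlation (adjusted p = 0.16, 0.133 and 0.0675 with an estimated correlation). Alpl, the alkaline phosphatase of mineralizing bone (ENSMUSG00000028766, chromosome 4, 137741733 to 137796384), was at 128 ± 8.14 CPM in WT and 32 ± 1.92 in KO, a log2 change of -2.00 ± 0.07. Runx2, the transcription factor that specifies osteoblasts (ENSMUSG00000039153, chromosome 17, 44495987 to 44814797), was higher in KO by 0.63 ± 0.08, with 20.6 ± 1.5 and 31.8 ± 1.05 CPM. Cdh11, a cadherin of osteoblasts, was lower by -3.74 ± 0.13 and Msx2, a homeobox factor of bone and skin, higher by 2.89 ± 0.20. Sox9, the transcription factor of cartilage (ENSMUSG00000000567, chromosome 11, 112782224 to 112787760), was higher by 4.10 ± 0.16, at 1.77 ± 0.297 and 30.5 ± 2.22 CPM. The largest edgeR adjusted p of these 5 genes was 6e-06. Col1a1, the main chain of bone collagen, stood at 1004 ± 51.5 CPM in WT and 970.7 ± 13.9 in KO, a difference within the replicate spread (edgeR adjusted p = 0.506). Correction for gene length and GC content turned this log2 change from -0.05 to 0.08, which then passed the threshold. Of 21 tested osteoblast differentiation genes, 5 were higher, 7 lower and 9 did not pass, or 5 and 6 when adjusted over the list alone, and the list did not move as a whole (camera adjusted p = 0.541). The osteoblast genes Sp7, Bglap, Ibsp and Dmp1 stayed under the expression filter, with at most 4, 25, 3 and 4 counts over any group.

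Of the 15296 genes tested, 9653 differed between KO and WT at day 14, with 4727 higher and 4926 lower, and 1463 and 1774 of these by 2-fold or more (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among the genes chosen for size, 3 had no count in WT. Klra4, a natural killer cell receptor of the Ly49 family (ENSMUSG00000079852, chromosome 6, 130043731 to 130067271), was at least 553-fold higher in KO at 25.8 ± 1.33 CPM, although close copies of it make its counts uncertain. Slc6a12, a betaine and GABA transporter, was at least 523-fold higher, and the kinase gene Sgk2 at least 257-fold higher. Fam111a, a nuclear protease (ENSMUSG00000024691, chromosome 19, 12545740 to 12589768), was higher by 10.69 ± 0.59, at 0.0931 ± 0.0462 CPM in WT and 161 ± 4.56 in KO. The protease inhibitor Spink8 had a KO to WT ratio of 907 (95% counting interval 162 to 35900), and P-selectin, Selp (ENSMUSG00000026580, chromosome 1, 164115264 to 164150026), was higher by 9.12 ± 0.53. In the other direction, 6 genes had no count in KO. Zic1, a zinc finger factor of early patterning (ENSMUSG00000032368, chromosome 9, 91358058 to 91365810), was at least 1230-fold lower. Fam213b, the cell cycle inhibitor Cdkn1c, the ubiquitin ligase Rnf144a, Rps4l, a copy of a ribosomal protein gene with uncertain counts, and the limb patterning gene Hoxa11 were lower by at least 598-fold, 512-fold, 500-fold, 306-fold and 286-fold.

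Among the gene lists at day 14, 9 of 14 smooth muscle and contractile genes were higher in KO and 2 lower, as many when adjusted over the list alone, with a median log2 change of 1.59 (camera adjusted p = 0.00796; adjusted p = 0.16 with an estimated correlation). Acta2 rose by 4.24 ± 0.07 and the myosin light chain Myl9 by 2.83 ± 0.13, while tropomyosin Tpm1 was lower by -0.34 ± 0.05. Targets of the actin-regulated factors SRF and MRTF had 15 of 25 higher and 8 lower, the same adjusted over the list alone (camera adjusted p = 0.0327; adjusted p = 0.116 with an estimated correlation). Fhl1 was at 2.38 ± 0.09 and the immediate early factor Egr1 at -1.12 ± 0.07. Adipocyte genes had 9 of 15 higher and 2 lower, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.0417; adjusted p = 0.133 with an estimated correlation). The lipid droplet gene Plin4 rose by 6.29 ± 0.28 and the fatty acid binding protein Fabp4 by 4.93 ± 0.15. The adipocyte list members Adipoq, Plin1, Cidec, Cd36, Lep, Retn, Cfd and Agt stayed under the expression filter. They had at most 1, 4, 1, 14, 1, 22, 11 and 7 counts over any group, so the call does not cover them. Wnt pathway genes had 21 of 29 lower and 5 higher, or 21 and 6 adjusted over the list alone (camera adjusted p = 0.00796; adjusted p = 0.0675 with an estimated correlation). The secreted Wnt inhibitors Sfrp1 and Sfrp2 were lower by -4.85 ± 0.15 and -7.01 ± 0.65, and Axin2, a feedback inhibitor and common readout of Wnt signalling, was higher by 2.57 ± 0.23.

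Interferon response genes were higher in 18 of 26 and lower in 4, or 19 and 4 adjusted over the list alone, the only one of the 10 lists passed by camera at day 14 that also passed with an estimated correlation (camera adjusted p = 3.26e-04; adjusted p = 0.0276 with an estimated correlation). Rsad2 (viperin) rose by 2.67 ± 0.09 and Ifi44 by 2.74 ± 0.09, while the membrane restriction factor Bst2 fell by 0.61 ± 0.12. All but 1 of 12 mitochondrially encoded genes were higher and none lower, as when adjusted over the list alone (camera adjusted p = 1.81e-05; adjusted p = 0.131 with an estimated correlation), beside the higher mitochondrial share of all KO libraries. Hypoxia response genes had 10 of 16 higher and 2 lower (camera adjusted p = 0.00796; adjusted p = 0.0675 with an estimated correlation), and glycolysis genes 11 of 18 higher and 4 lower (camera adjusted p = 0.0417; adjusted p = 0.429 with an estimated correlation), with the same counts adjusted over the list alone. The glucose transporter Slc2a1, in both lists, rose by 1.65 ± 0.04 and the lactate exporter Slc16a3 fell by 6.09 ± 0.17. Glucocorticoid response genes had 12 of 19 higher and 5 lower, the same adjusted over the list alone (camera adjusted p = 0.0327; adjusted p = 0.249 with an estimated correlation). Glutamine synthetase Glul was at 1.69 ± 0.05 and Fkbp5, a standard reporter of the receptor, at 0.80 ± 0.05. Inflammatory cytokine genes had 13 of 21 lower and 5 higher, the same adjusted over the list alone (camera adjusted p = 0.0417; adjusted p = 0.249 with an estimated correlation). The receptor gene Il1rl1 fell by 6.39 ± 0.14 and its ligand Il33 rose by 1.82 ± 0.07. Correction for gene length and GC content ended the call of the inflammatory list (camera adjusted p = 0.105). Among single genes, Pparg, the adipocyte master regulator, was at 0.65 ± 0.26 (edgeR adjusted p = 0.0373), a call lost with the replicate number as a block (0.0539) or without KO replicate 1 (0.0911) or 3 (0.113) or WT replicate 1 (0.0826) or 3 (0.165).

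**Figure D2:**
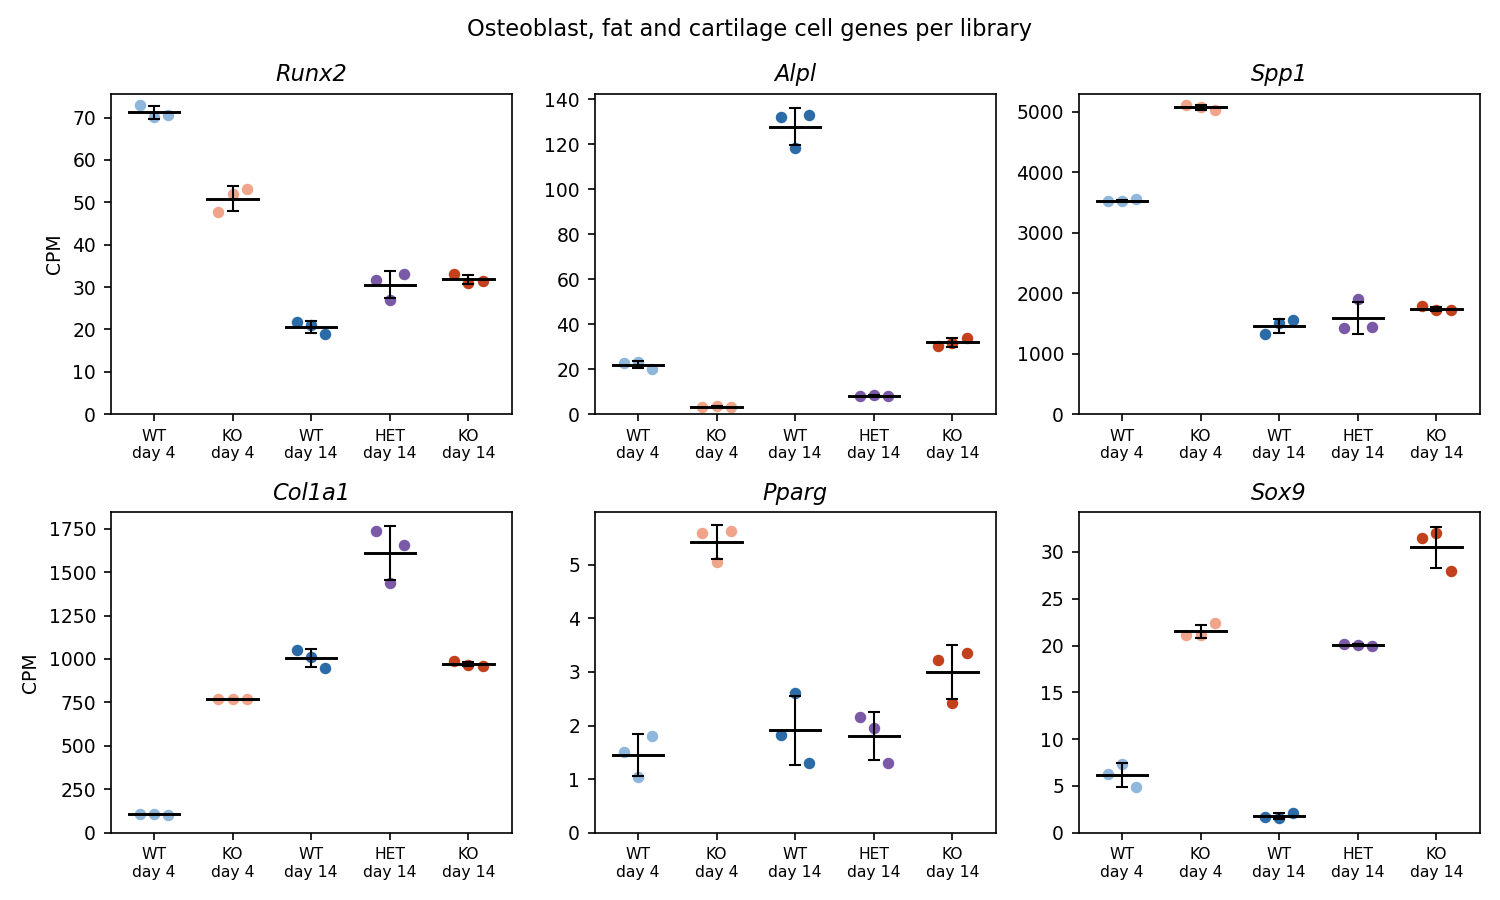
CPM of Runx2, Alpl, Spp1, Col1a1, Pparg and Sox9 in each group, with 1 point per library, a line at the group mean and an error bar of 1 SD. Alpl is highest in WT at day 14 (128 CPM) and Sox9 lowest there (1.77 CPM).

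At day 14, the HET libraries held transcripts that WT and KO nearly lacked, with far higher interferon genes and far lower Alpl. The labels name no embryo or culture. A different origin of the cells thus cannot be told apart from the copies of Actb in any comparison of genotypes. Col1a2, the second chain of type I collagen (ENSMUSG00000029661, chromosome 6, 4504814 to 4541544), stood at 489.5 ± 37.0 CPM in HET against 0.310 ± 0.163 in WT and 0.117 ± 0.0987 in KO, a HET to WT change of 10.60 ± 0.35. Xist, the RNA that silences an X chromosome (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), stood at 162 ± 53.2 CPM in HET, 3530 times its level in WT (95% counting interval 1210 to 17100). Alpl fell to 8.29 ± 0.213 CPM, a change of -3.95 ± 0.08 from WT. Sox9 was higher by 3.50 ± 0.16, Col1a1 by 0.68 ± 0.06 and Runx2 by 0.57 ± 0.08. Of the 5 genes tested by fold here, the largest edgeR adjusted p was 1.83e-05. In all, 8910 genes differed between HET and WT, with 4330 higher and 4580 lower, and 1121 and 1757 by 2-fold or more (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Osteoblast differentiation genes had 7 of 21 higher and 9 lower, the same adjusted over the list alone, with a median of 0.12, a mean of -0.38 and a test in the direction of the mean (camera adjusted p = 0.983).

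Fam111a was again among the largest increases in HET, by 10.95 ± 0.59, with the protease inhibitor Ctla2a at 8.18 ± 0.77, the antiviral enzyme Oas2 at 7.92 ± 0.26 and Cybb, the catalytic subunit of the phagocyte oxidase, at 7.69 ± 0.47. Zic1 and Rps4l were again among the largest decreases, with WT to HET ratios of 1080 (95% counting interval 370 to 5250) and 805 (144 to 31800). The flippase gene Atp9a had a WT to HET ratio of 360 (99.4 to 2980). The cytokine Il19 was lower by -8.36 ± 0.65, Fam213b by -7.97 ± 0.61 and the growth factor midkine, Mdk, by -7.88 ± 0.62. Interferon response genes were higher in 24 of 26 and lower in 1, the same adjusted over the list alone (camera adjusted p = 1.17e-14; adjusted p = 1.4e-04 with an estimated correlation), and Ifi44 rose by 3.77 ± 0.09. Cholesterol synthesis genes were lower in 16 of 21 and higher in 3, the same adjusted over the list alone (camera adjusted p = 8.54e-05; adjusted p = 0.00999 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, fell by 0.84 ± 0.04, and Stard4, a sterol carrier, rose by 0.47 ± 0.05. Fibroblast and mesenchymal genes had 10 of 13 higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.00669; adjusted p = 0.071 with an estimated correlation). Ly6a was at 4.16 ± 0.11 and the mesenchymal factor Twist1 at -0.78 ± 0.09.

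Glycolysis genes had 13 of 18 higher and 3 lower in HET, the same adjusted over the list alone (camera adjusted p = 0.00591; adjusted p = 0.392 with an estimated correlation). The aldolase gene Aldoa was at 1.08 ± 0.07. The mitochondrially encoded genes had 10 of 12 higher, or 11 adjusted over the list alone (camera adjusted p = 6.1e-04; adjusted p = 0.285 with an estimated correlation), beside a mitochondrial share above that of WT. That call ended with correction for length and GC content (camera adjusted p = 0.0642). Wnt pathway genes had 19 of 29 lower and 5 higher, or 20 and 5 adjusted over the list alone (camera adjusted p = 0.0145; adjusted p = 0.0854 with an estimated correlation). The transcription factor Tcf7 was at -2.06 ± 0.10 and Dkk3 at 3.32 ± 0.18. HET replicate 2 stood apart from replicates 1 and 3, with a chi-square per degree of freedom of 55.6 and 55.8 against 2.96 between those 2, and it held the highest ribosomal protein share. Without it the Wnt list no longer passed (camera adjusted p = 0.0654), while 10083 genes differed.

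KO cells differed from HET cells at day 14 in higher cholesterol synthesis genes and lower interferon response genes. The smooth muscle, adipocyte, and collagen and matrix lists also passed, but not with an estimated correlation (adjusted p = 0.208, 0.0815 and 0.539 with an estimated correlation). Acta2 was higher in KO by 2.70 ± 0.07, Alpl by 1.95 ± 0.09 and Plin4 by 7.18 ± 0.37, and Col1a1 was lower by -0.73 ± 0.06 and Mmp13, a collagenase of bone and cartilage, by -6.59 ± 0.05 (4162 ± 113 CPM in HET, 43.1 ± 1.33 in KO). Actb was lower in KO by -5.09 ± 0.06, and the largest edgeR adjusted p of these 6 genes was 6.05e-08. Runx2 did not separate the groups, at 31.8 ± 1.05 CPM in KO and 30.6 ± 3.21 in HET (edgeR adjusted p = 0.574). In total 9104 genes differed, 4502 higher in KO and 4602 lower, with 1519 and 1378 by 2-fold or more (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Osteoblast differentiation genes were higher in 5 of 21 and lower in 9, the same adjusted over the list alone (camera adjusted p = 0.651).

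Klra4 and Spink8 had no count in HET and were at least 533-fold and at least 292-fold higher in KO. Sulf1, a heparan sulfate sulfatase (ENSMUSG00000016918, chromosome 1, 12692277 to 12861192), had a KO to HET ratio of 2930 (95% counting interval 526 to 116000), the homeobox gene Hoxd8 of 1060 (191 to 42100) and Slc6a12 of 756 (209 to 6250). Selp was higher by 10.40 ± 0.84. Absent from the KO libraries were the homeobox gene Irx1 (ENSMUSG00000060969, chromosome 13, 71957921 to 71963723), at least 1840-fold lower, Hoxa11, at least 445-fold lower, Dmrt2, at least 292-fold lower, and the raft protein gene Rftn1, at least 239-fold lower. Xist had a HET to KO ratio of 11700 (2090 to 461000) and Col1a2 a change of -12.02 ± 0.55.

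In the lists, 21 of 26 interferon response genes were lower in KO than in HET and 3 higher, the same adjusted over the list alone (camera adjusted p = 5.18e-08; adjusted p = 0.00189 with an estimated correlation). Oas2 was at -4.39 ± 0.13. Cholesterol synthesis genes were higher in 19 of 21 and lower in none, the same adjusted over the list alone (camera adjusted p = 1e-06; adjusted p = 0.00269 with an estimated correlation). Idi1 was at 1.49 ± 0.07. The remaining 6 calls were lost with an estimated correlation. Smooth muscle and contractile genes were higher in 10 of 14 and lower in 2 (camera adjusted p = 0.0053; adjusted p = 0.208 with an estimated correlation), SRF and MRTF targets higher in 17 of 25 and lower in 6 (0.00814; adjusted p = 0.0516 with an estimated correlation), and adipocyte genes higher in 10 of 15 and lower in 2 (0.016; adjusted p = 0.0815 with an estimated correlation). Targets of YAP and TEAD, factors of cell shape and stiffness, were higher in 11 of 18 and lower in 2 (camera adjusted p = 0.021; adjusted p = 0.383 with an estimated correlation). Ccn2 was at 1.80 ± 0.12 and Ajuba at -0.63 ± 0.08. Collagen and matrix genes were lower in 18 of 32 and higher in 7 (camera adjusted p = 0.016; adjusted p = 0.539 with an estimated correlation), with the proteoglycans Bgn at -8.77 ± 0.17 and Dcn at -3.96 ± 0.06 and the collagen gene Col8a1 at 2.05 ± 0.05. These 5 lists had the same counts adjusted over the list alone. Mitochondrially encoded genes were higher in 8 of 12, or 9 adjusted over the list alone (camera adjusted p = 0.0174; adjusted p = 0.386 with an estimated correlation), beside the higher mitochondrial share of KO.

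At day 4, KO cells already had higher tested genes of the smooth muscle and contractile list, and lower interferon and immediate early genes, than WT. Of the smooth muscle list, Myh11 and Myocd stayed under the expression filter, with 16 and 2 counts over KO and 7 and 18 over WT at day 4. Acta2 was higher in KO by 12.29 ± 0.22 and Myl9 (ENSMUSG00000067818, chromosome 2, 156775420 to 156781658) by 11.28 ± 0.34, at 0.164 ± 0.142 CPM in WT and 479 ± 7.38 in KO. Col1a1 was higher in KO by 2.84 ± 0.06, Sox9 by 1.78 ± 0.11 and Pparg by 1.92 ± 0.24. Alpl was lower by -2.70 ± 0.09, Runx2 by -0.49 ± 0.07 and Tnfsf11, the osteoclast-inducing cytokine RANKL, by -9.09 ± 0.26 (224 ± 0.836 CPM in WT, 0.397 ± 0.204 in KO). The largest edgeR adjusted p of these 8 genes was 2.34e-05. In total 10630 genes differed, 5455 higher in KO and 5175 lower, with 2526 and 1815 by 2-fold or more (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). All 21 osteoblast differentiation genes passed, 11 higher and 10 lower, the same adjusted over the list alone, with a median of 0.20, a mean of -0.28 and a test in the direction of the median (camera adjusted p = 0.967).

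Fam111a, Ldb3, a protein of the muscle Z-disc, and Klra4 had no count in WT at day 4 and were at least 2090-fold, 460-fold and 365-fold higher in KO. Genes without a count in KO were Zic1, at least 2820-fold lower, Auts2 (ENSMUSG00000029673, chromosome 5, 131437333 to 132543344), at least 979-fold lower, the potassium channel gene Kcnk5, at least 876-fold, Rnf144a, at least 853-fold, Rps4l, at least 482-fold, and the heparan sulfate enzyme gene Hs3st1, at least 426-fold. Smooth muscle and contractile genes were higher in 13 of 14 and lower in 1, the same adjusted over the list alone (camera adjusted p = 3.68e-06; adjusted p = 0.0267 with an estimated correlation). SRF and MRTF targets were higher in 21 of 25 and lower in 3, the same adjusted over the list alone (camera adjusted p = 8.93e-07; adjusted p = 0.00421 with an estimated correlation). Egr1 was at -2.51 ± 0.07. The smooth muscle list and the SRF and MRTF list share members, so their calls are not independent. Genes of actin binding and turnover were higher in 23 of 35 and lower in 6, the same adjusted over the list alone (camera adjusted p = 0.00153; adjusted p = 0.0673 with an estimated correlation). The severing protein gelsolin, Gsn, was at 3.02 ± 0.06 and Tpm3 at -1.05 ± 0.05. Cholesterol synthesis genes were higher in 16 of 21 and lower in 4, the same adjusted over the list alone (camera adjusted p = 0.0036; adjusted p = 0.036 with an estimated correlation). Mvd was at 1.79 ± 0.07 and Cyp51 at -0.36 ± 0.05.

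Lower at day 4 were all 11 immediate early genes, the same adjusted over the list alone (camera adjusted p = 1.26e-06; adjusted p = 0.00447 with an estimated correlation). Atf3 was at -2.86 ± 0.06 and Jun at -2.52 ± 0.05. Interferon response genes were lower in 22 of 26 and higher in 3, the same adjusted over the list alone (camera adjusted p = 2.77e-05; adjusted p = 0.00534 with an estimated correlation). Ifit1 was at -6.36 ± 0.16 and the signalling factor Stat2 at 0.88 ± 0.06. An estimated correlation did not keep the next calls. Of 20 unfolded protein and amino acid stress genes, 16 were lower and 2 higher (camera adjusted p = 8.93e-07; adjusted p = 0.169 with an estimated correlation). Of 16 cAMP response genes, 11 were lower and 4 higher (camera adjusted p = 0.0112; adjusted p = 0.241 with an estimated correlation). Of 12 imprinted genes, 11 were lower and 1 higher (camera adjusted p = 0.0023; adjusted p = 0.0719 with an estimated correlation). Of 21 inflammatory cytokine genes, 14 were lower and 6 higher (camera adjusted p = 0.0264; adjusted p = 0.195 with an estimated correlation). Among them, the glutathione-degrading enzyme Chac1 was at -2.40 ± 0.05, the orphan receptor Nr4a1 at -4.21 ± 0.07, the growth inhibitor Plagl1 at -3.56 ± 0.13 and the prostaglandin synthase Ptgs2 at -3.26 ± 0.04. Mitochondrially encoded genes were higher in 11 of 12, or 12 adjusted over the list alone (camera adjusted p = 6.34e-04; adjusted p = 0.195 with an estimated correlation), and nuclear-encoded respiratory chain genes in 34 of 44 with 1 lower (camera adjusted p = 2.04e-04; adjusted p = 0.688 with an estimated correlation). The other lists of this paragraph had the same counts adjusted over the list alone. Correction for length and GC content ended the inflammatory call (camera adjusted p = 0.0652).

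Between days 4 and 14, WT cells raised Col1a1, Alpl and the vitamin D-degrading enzyme and lowered Runx2. Col1a1 rose by 3.23 ± 0.06, from 107 ± 3.32 to 1004 ± 51.5 CPM, and Alpl by 2.53 ± 0.07. Cyp24a1, the vitamin D 24-hydroxylase (ENSMUSG00000038567, chromosome 2, 170482708 to 170497145), rose by 11.18 ± 0.33, from 0.171 ± 0.112 to 446 ± 8.19 CPM. Runx2 fell by 1.79 ± 0.08, osteopontin, Spp1, by 1.27 ± 0.09 and Sox9 by 1.82 ± 0.17. Actb rose by 1.34 ± 0.05, and the largest edgeR adjusted p of these 7 genes was 3.87e-08. In total 11410 genes changed, 6075 upward and 5335 downward, with 3195 and 2043 by 2-fold or more (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Osteoblast differentiation genes rose in 8 of 21 and fell in 8, the same adjusted over the list alone (camera adjusted p = 0.918).

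Keratin 17, Krt17 (ENSMUSG00000035557, chromosome 11, 100256217 to 100261029), had a day 14 to day 4 ratio in WT of 8380 (95% counting interval 1500 to 331000), and the glutathione transferase Mgst2 of 621 (171 to 5140). The histone gene Hist1h2ap, whose near-identical copies make its counts uncertain, was at least 690-fold higher. Vnn3 rose by 9.10 ± 0.58 and Cited4 by 7.44 ± 0.72. The scavenger receptor Olr1 (ENSMUSG00000030162, chromosome 6, 129485244 to 129507165) fell by 7.69 ± 0.49, Flrt2 by 6.87 ± 0.49, the adhesion molecule Alcam by 6.80 ± 0.13, the sodium pump subunit Atp1b1 by 6.02 ± 0.14, Cnnm1 by 5.84 ± 0.42 and the serotonin receptor Htr1b by 5.83 ± 0.48. Interferon response genes rose in 21 of 26 and fell in 2, the same adjusted over the list alone (camera adjusted p = 8.24e-04; adjusted p = 0.0465 with an estimated correlation). Gbp2 was at 3.86 ± 0.09 and Rsad2 at -1.95 ± 0.09. The other 5 calls were lost with an estimated correlation and had the same counts adjusted over the list alone. Of 44 nuclear-encoded respiratory chain genes 39 rose and 1 fell (camera adjusted p = 1.88e-05; adjusted p = 0.668 with an estimated correlation), and of 32 Hox genes 25 rose and none fell (camera adjusted p = 0.00471; adjusted p = 0.267 with an estimated correlation), beside the higher ribosomal protein share of the WT libraries of day 14. Of 14 smooth muscle and contractile genes 10 rose and 1 fell (camera adjusted p = 0.0417; adjusted p = 0.267 with an estimated correlation). Of 16 cAMP response genes 14 fell and 2 rose (camera adjusted p = 1.2e-04; adjusted p = 0.244 with an estimated correlation), with Gem at -3.23 ± 0.07, and of 20 unfolded protein and amino acid stress genes 15 fell and 4 rose (camera adjusted p = 0.00166; adjusted p = 0.374 with an estimated correlation). Chac1 was at -1.78 ± 0.05. The Hox call ended with correction for length and GC content (camera adjusted p = 0.165), and the smooth muscle call ended without WT replicate 3 of day 14 (camera adjusted p = 0.0591).

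In KO cells the change with time was led by interferon-induced genes, some without a single count at day 4. Cmpk2 (ENSMUSG00000020638, chromosome 12, 26469204 to 26479837), Cxcl9 and Mx1 had no count in KO at day 4 and were at least 672-fold, 470-fold and 361-fold higher at day 14. Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452) had a day 14 to day 4 ratio of 3610 (95% counting interval 1000 to 29900) and the GTPase Iigp1 of 4580 (821 to 181000). Alpl rose by 3.24 ± 0.09, Sox9 by 0.50 ± 0.11 and Col1a1 by 0.33 ± 0.06, while Runx2 fell by 0.68 ± 0.08, Spp1 by 1.54 ± 0.09, Acta2 by 2.11 ± 0.07 and Actb by 1.59 ± 0.06. Actg1 did not pass, at 0.11 ± 0.10 (edgeR adjusted p = 0.384), and the largest edgeR adjusted p of the 7 genes before it was 6.98e-04. In total 9316 genes changed, 4712 upward and 4604 downward, with 1611 and 1560 by 2-fold or more (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Osteoblast differentiation genes rose in 5 of 21 and fell in 11, the same adjusted over the list alone (camera adjusted p = 0.254).

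Auts2 had no count in KO at day 4 and was at least 455-fold higher at day 14. Cnnm1 had a day 4 to day 14 ratio of 3460 (621 to 137000), the sterol exporter Abcg1 of 395 (109 to 3270), Accsl of 385 (106 to 3180) and Rnf182 of 376 (128 to 1820), and Olfm1 and Col23a1 fell by 9.40 ± 0.60 and 8.38 ± 0.54. Interferon response genes rose in 25 of 26, the same adjusted over the list alone, with a median of 5.60 (camera adjusted p = 4.63e-15; adjusted p = 1.23e-04 with an estimated correlation). Cholesterol synthesis genes fell in 18 of 21 and rose in 1, or 18 and 2 adjusted over the list alone (camera adjusted p = 1.6e-07; adjusted p = 0.00166 with an estimated correlation). The next 5 calls were also kept. Of 25 SRF and MRTF targets, 19 fell and 4 rose (camera adjusted p = 8.15e-07; adjusted p = 0.00166 with an estimated correlation). Of 14 smooth muscle and contractile genes, 10 fell and 2 rose (camera adjusted p = 9.01e-05; adjusted p = 0.0367 with an estimated correlation). Of 11 immediate early genes, 10 rose and 1 fell (camera adjusted p = 1.92e-04; adjusted p = 0.0125 with an estimated correlation). Of 22 matrix proteases and inhibitors, 15 rose and 4 fell (camera adjusted p = 0.00156; adjusted p = 0.0367 with an estimated correlation). Of 16 hypoxia response genes, 9 rose and 2 fell, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.00395; adjusted p = 0.0367 with an estimated correlation). Mmp13 rose by 2.89 ± 0.07, the stress factor Zfp36 by 1.66 ± 0.06 and hexokinase Hk2 by 2.07 ± 0.07, while the protease inhibitor Timp3 fell by 3.40 ± 0.18.

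The remaining 7 calls in KO over time were lost with an estimated correlation. Of 21 inflammatory cytokine genes, 15 rose and 3 fell, or 16 and 4 adjusted over the list alone (camera adjusted p = 0.00298; adjusted p = 0.072 with an estimated correlation). Of 20 unfolded protein and amino acid stress genes, 11 rose and 3 fell (camera adjusted p = 0.00395; adjusted p = 0.398 with an estimated correlation). Of 7 tested osteocyte genes, 6 rose and 1 fell (camera adjusted p = 0.00547; adjusted p = 0.0624 with an estimated correlation). The list members Sost, Dmp1, Mepe, Fgf23 and Dkk1 stayed under the filter, with at most 3, 4, 5, 21 and 3 counts over any group. The call thus does not cover them. Of 18 glycolysis genes, 11 rose and 3 fell, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.008; adjusted p = 0.341 with an estimated correlation). Of 19 glucocorticoid response genes, 13 rose and 5 fell (camera adjusted p = 0.015; adjusted p = 0.165 with an estimated correlation). Of 32 collagen and matrix genes, 20 fell and 8 rose (camera adjusted p = 0.00298; adjusted p = 0.425 with an estimated correlation). Of 4 actin isoform genes, 3 fell (camera adjusted p = 0.00547; adjusted p = 0.0624 with an estimated correlation). Counts adjusted over the list alone were the same where none is given. Il33 rose by 5.64 ± 0.08, Pdpn, a membrane protein of the osteocyte list, by 1.74 ± 0.05 and Glul by 2.16 ± 0.05, and Col6a3 fell by 5.35 ± 0.21.

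The change with time differed between KO and WT for 9897 genes, 4692 with a higher and 5205 with a lower change in KO, and 2116 and 2939 of these by 2-fold or more (edgeR's quasi-likelihood test of the interaction with Benjamini-Hochberg adjustment). Interferon-induced Rsad2 rose in KO and fell in WT, with an interaction of 13.47 ± 1.03. The contractile genes Acta2 and Myl9 fell in KO and rose in WT. Acta2 was at -8.06 ± 0.23 and Myl9 at -8.45 ± 0.37. Sulf1 was at 13.82 ± 1.26 and Olr1 at 12.83 ± 0.78. Peg3, an imprinted zinc finger gene, and Auts2 had no count in KO at day 4, so their fitted interactions of 13.36 and 12.71 depend on the prior count and bound nothing, and the same holds for Actg2 at -7.11, absent from WT at day 4. Krt17 was at -11.60 ± 1.56, the glutamate receptor gene Gria3 (ENSMUSG00000001986, chromosome X, 41400854 to 41678601) at -9.87 ± 1.13, Pianp at -8.88 ± 0.60 and Cyba, a subunit of the phagocyte oxidase (ENSMUSG00000006519, chromosome 8, 122424776 to 122432930), at -8.39 ± 0.40. Among bone genes, Runx2 fell less in KO (1.11 ± 0.11), Alpl rose more (0.71 ± 0.12) and Col1a1 rose less (-2.89 ± 0.09). Among the genes given with an SE here, the largest edgeR adjusted p was 5.95e-05. Osteoblast differentiation genes were higher in 6 of 21 and lower in 12, the same adjusted over the list alone (camera adjusted p = 0.643).

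In the interaction, 23 of 26 interferon response genes were higher and 1 lower (camera adjusted p = 3.71e-08; adjusted p = 0.00176 with an estimated correlation), 8 of 11 immediate early genes higher and 1 lower (camera adjusted p = 9.43e-04; adjusted p = 0.0373 with an estimated correlation) and 17 of 25 SRF and MRTF targets lower and 4 higher (camera adjusted p = 0.0028; adjusted p = 0.0373 with an estimated correlation). These 3 of the 13 calls were kept with an estimated correlation. Of 20 unfolded protein and amino acid stress genes, 16 had a higher change in KO and 3 a lower (camera adjusted p = 1.04e-05; adjusted p = 0.193 with an estimated correlation). Of 16 cAMP response genes, 14 had a higher change in KO and 1 a lower (camera adjusted p = 1.12e-04; adjusted p = 0.0704 with an estimated correlation). Of 7 tested osteocyte genes, which leave out Sost, Dmp1, Mepe, Fgf23 and Dkk1, 6 had a higher change in KO and 1 a lower (camera adjusted p = 0.00497; adjusted p = 0.0635 with an estimated correlation). Of 16 hypoxia response genes, 8 had a higher change in KO and 3 a lower (camera adjusted p = 0.0136; adjusted p = 0.0691 with an estimated correlation). Of 19 glucocorticoid response genes, 11 had a higher change in KO and 5 a lower (camera adjusted p = 0.0257; adjusted p = 0.193 with an estimated correlation). Of 14 smooth muscle and contractile genes, 11 had a lower change in KO and 1 a higher (camera adjusted p = 1.31e-04; adjusted p = 0.0635 with an estimated correlation). Of 44 nuclear-encoded respiratory chain genes, 28 had a lower change in KO and 3 a higher (camera adjusted p = 0.00354; adjusted p = 0.701 with an estimated correlation). Of 4 actin isoform genes, 4 had a lower change in KO (camera adjusted p = 0.0071; adjusted p = 0.0704 with an estimated correlation). Of 30 proliferation genes, 16 had a lower change in KO and 5 a higher (camera adjusted p = 0.0453; adjusted p = 0.179 with an estimated correlation). Of 32 Hox genes, 17 had a lower change in KO and 5 a higher (camera adjusted p = 0.0494; adjusted p = 0.314 with an estimated correlation). The respiratory chain and Hox calls stand beside a ribosomal protein share that went from 2.22% to 3.15%, 3.57% and 3.94% in WT and from 2.27% to 2.08%, 2.06% and 2.07% in KO. All 13 had the same counts adjusted over the list alone. Chac1 was at 3.42 ± 0.07, Pde4b at 3.17 ± 0.10, Pdpn at 4.48 ± 0.06, Ccnb2 at -2.65 ± 0.11 and Hoxc6 at -2.40 ± 0.13. The proliferation call ended with another scaling (camera adjusted p = 0.0559), and the Hox call ended with the replicate number as a block (0.0532), with correction for length and GC content (0.23) and without WT replicate 3 of day 14 (0.0606).

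**Figure D3:**
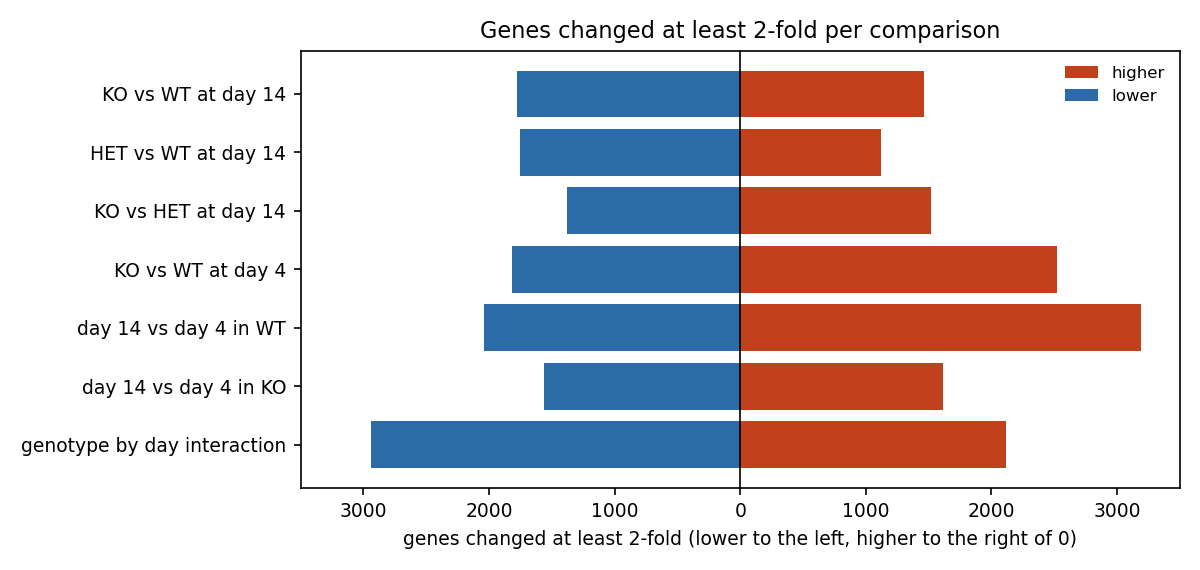
Number of genes past the threshold with a change of 2-fold or more in each comparison, with bars for higher and lower genes. WT over time has the most higher genes (3195) and the interaction the most lower genes (2939).

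**Figure D4:**
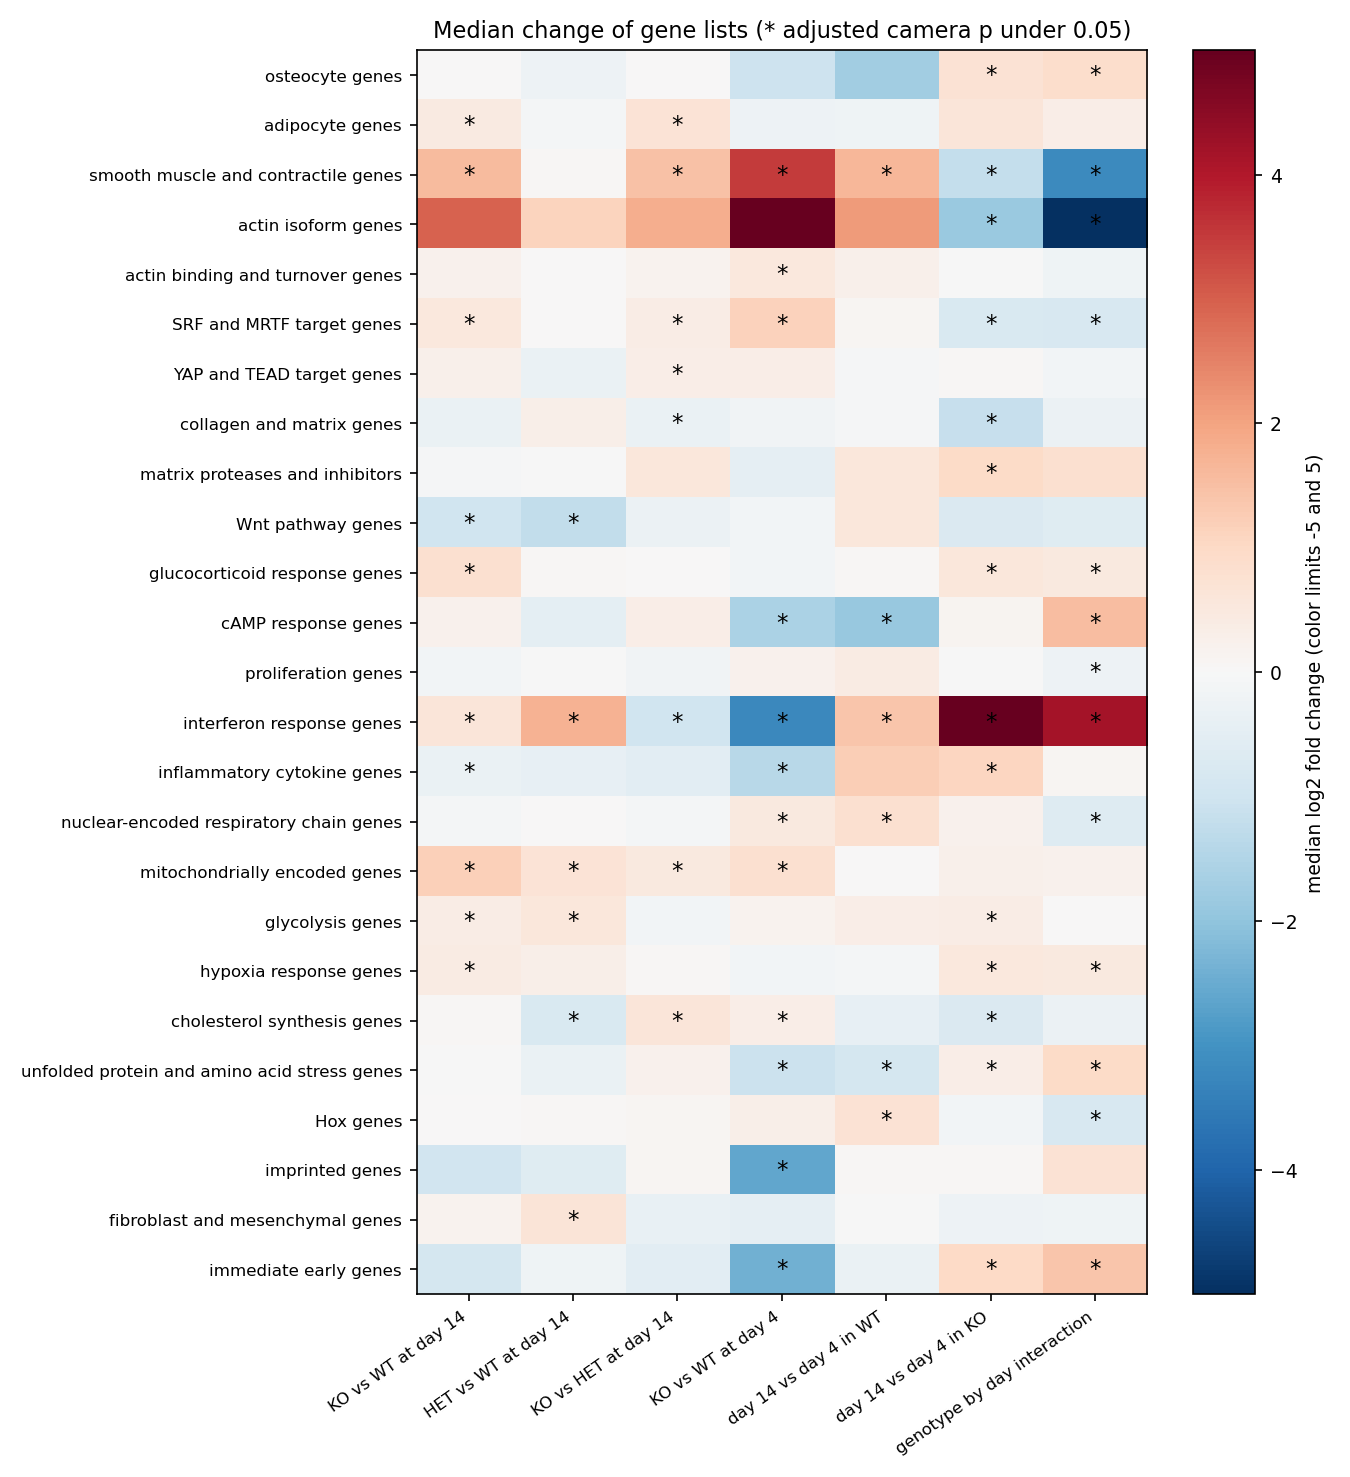
Median log2 fold change over the tested members of each gene list called at least once, by comparison, with a star where the adjusted camera p was under 0.05; the color scale ends at -5 and 5. The interferon response genes stand at 5.6 in KO over time and at -3.21 in KO against WT at day 4.

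Comparisons shared part of their changes. Between KO and WT, 1748 genes differed by 2-fold or more at both days, and 69.3% of them with the same sign: 596 were higher at both days and 616 lower, against 242 and 211 for independent lists, and 536 had opposite signs. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.387 and Spearman's rho 0.123. Over time, 1831 genes changed by 2-fold or more in both WT and KO, 69.1% with the same sign, with r of 0.266 and rho of 0.23. At day 14, 1709 genes differed from WT by 2-fold or more in both KO and HET, 87.0% with the same sign (528 higher and 959 lower, against 107 and 204 for independent lists), with r of 0.529 and rho of 0.464. Both of these comparisons used the same 3 WT libraries, and simulated groups without any effect gave r of 0.499 and no shared gene. The covariance was 1.07 against 0.04 in the simulation, and shared controls add the same covariance with or without real effects. The WT libraries are too few to be split between the 2 comparisons, so part of the excess of shared genes over independent lists may come from the shared controls.

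Without a camera call in any of the 7 comparisons were 14 lists. They were osteoblast differentiation genes, mineralization regulators, osteoclast, chondrocyte, skeletal muscle, neuron, macrophage, endothelial and epithelial genes, BAF and Polycomb complex genes, BMP and TGF-beta pathway genes, p53 and senescence genes and nuclear and non-polyadenylated RNAs. Single members did differ. Mgp, an inhibitor of calcification, was higher in KO than in WT at day 14 by 7.85 ± 0.48, from 0.233 ± 0.0811 to 54.9 ± 1.8 CPM, and Smarca4, the ATPase of the BAF complex, was lower by -0.16 ± 0.04. Cd68, a lysosomal protein abundant in macrophages, was higher by 2.59 ± 0.10. The largest edgeR adjusted p of these 3 genes was 0.00316. The proliferation marker Mki67 did not separate KO from WT at day 14, at 187 ± 23.4 CPM in WT and 211 ± 7.7 in KO (edgeR adjusted p = 0.211).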

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

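The tests of RNA mixed in from WT libraries, of the axis shared with WT replicates, of all 3 explanations for Actb, and of immune cells and a shared day batch for the interferon genes were chosen only after the result was seen. The test of the interaction flagged every result of the next paragraph. Groups of 3 samples are too small for the outlier check.

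The change between day 4 and day 14 differed between KO and WT for 9897 genes. The interactions (log2) were -2.93 for Actb, -0.77 for Actg1, -8.06 for Acta2 and -7.11 for Actg2. Those of the largest genes were 13.82 for Sulf1, 13.47 for Rsad2, 13.36 for Peg3, 12.83 for Olr1, 12.71 for Auts2, -11.60 for Krt17, -9.87 for Gria3, -8.88 for Pianp, -8.45 for Myl9 and -8.39 for Cyba. List medians above 0 were 4.15 for interferon response genes, 0.94 for unfolded protein and amino acid stress genes, 1.55 for cAMP response genes, 1.39 for immediate early genes, 0.88 for osteocyte genes, 0.49 for hypoxia response genes and 0.47 for glucocorticoid response genes. Medians below 0 were -3.18 for smooth muscle and contractile genes, -0.80 for SRF and MRTF target genes, -0.63 for nuclear-encoded respiratory chain genes, -5.02 for actin isoform genes (the middle of Actb and Actg2, whose fitted value bounds nothing), -0.24 for proliferation genes and -0.80 for Hox genes.

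HET replicate 2 of day 14 stood apart from replicates 1 and 3. Its log2 ratio to them fell with exon length (Spearman rho -0.56), while replicates 1 and 3 differed with a rho of 0.07, so transcript length bias of the library is consistent with the difference. The ratio of WT replicate 3 to 1 of day 14 followed the same axis (Pearson r 0.63), also falling with length (rho -0.5). GC content left the matter open (rho 0.1), and WT RNA of day 14 mixed into the library is excluded, since 16 genes off in the other HET libraries stood at 0.61% of their WT level against 0.471% there. No biological explanation was tested.

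Actb counts remained in the KO libraries and were higher at day 4. Reads of Actg1 assigned to Actb are excluded as the source of the excess at day 4, since Actb changed from day 4 to day 14 by a log2 difference of -1.69 (SE 0.12) from Actg1; for the level left at day 14 they stay open. WT cells or RNA in the KO libraries of day 4 are excluded, since 10 genes on in WT at day 4 and off in KO at day 14 had a median of 0.04% of their WT level, against 11.4% for Actb. Transcripts of the disrupted allele remain possible at 1.49% of the WT level at day 14, which counts per gene cannot resolve. Reads of Acta2 or Actg2 assigned to Actb were not tested. Both genes also fell in KO from day 4 to day 14, Acta2 from 2116 to 489 CPM and Actg2 from 95.2 to 5.3 CPM.

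Interferon response genes rose in KO from day 4 to day 14. Immune cells as the source of these transcripts are excluded, since 6 macrophage genes summed to 0.015 CPM in KO at day 14 and Ptprc, a gene of all white blood cells read after its value was seen, had 1 count over that group. A day batch shared by both genotypes is excluded as the whole cause by the median interaction of 4.15, which cancels any shared part. The list also changed with day in WT, where 21 of 26 genes rose and 2 fell. A shared day or batch part of the rise in KO thus stays open. A batch touching only KO libraries was not tested. Length and GC bias is excluded, with a list median of 5.52 after correction and 5.60 before. The criterion of this test was written down beforehand, but the correction itself was chosen after the data were seen. A change in the KO cells themselves is consistent with these values; what set it off was not tested.

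Regrouping the libraries of each pairwise comparison gives 10 splits, too few for a share under 0.05; in each comparison only 1 split, the real one, reached its count. The highest count of another split was 2639 for HET against WT at day 14 and 0 for the others. For the interaction, 1 of 50 splits, the real one, reached 9897 genes, and the highest other was 5740. The other splits mixed KO and WT libraries of a day within a group, which widens the spread inside groups. They therefore cannot decide whether the count of the interaction came from a grouping by chance.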

How the results depend on the processing

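The correction for length and GC content, the sum of HET replicates 1 and 3 and the list tests without HET replicate 2 or WT replicate 3 of day 14 were chosen only after the result was seen. All 7 counts of genes stayed within 1.5 times under every alternative, from 0.752 times (HET against WT, only the groups compared, 6696 genes) to 1.178 times (KO over time, only the groups compared, 10972 genes). The genes called changed more than their number. After correction for length and GC content, 9564 of the 11410 genes of WT over time were called again with the same sign. For KO against WT at day 14 these were 8421 of 9653, and for KO over time 8821 of 9316. With 1 replicate left out, the counts ran from 8827 to 9628 for KO against WT at day 14, 8167 to 10083 for HET against WT, 8387 to 9554 for KO against HET, 9986 to 10172 for KO against WT at day 4, 10935 to 11259 for WT over time, 8585 to 8639 for KO over time and 9461 to 9934 for the interaction. The highest counts of both HET comparisons came without HET replicate 2. With the replicate number as a block the counts were 9551, 8783, 8999, 10538, 11310, 9241 and 9803 in the same order, and with HET replicates 1 and 3 summed they were 8510 for HET against WT and 9021 for KO against HET.

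Spearman's rho between the KO differences of day 14 and day 4 was 0.123 against Pearson's r of 0.387; the cause was not tested. Of 1079 values of named genes, DESeq2 kept 1077 calls as they were, RLE scaling 1077, the block 1078 and the correction for length and GC content 1055. With only the samples of the groups compared, 1053 were kept, 7 weakened and 4 strengthened, and genes under the filter of that fit were not compared. Leaving out replicates kept 7259, weakened 109 and strengthened 6. The block ended the call of Pparg in KO against WT at day 14 (edgeR adjusted p = 0.0539) and of the Hox genes in the interaction (camera adjusted p = 0.0532), brought that of the nuclear-encoded respiratory chain genes in KO over time (camera adjusted p = 0.0443), and changed no other call of a named gene or list.

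Only the correction for length and GC content turned directions, in 8 log2 values. In KO against WT at day 14, Col1a1 (not past the threshold as reported) was at 0.08, Cebpb at 0.13 and Csrp1 at 0.05. In WT over time, Capg was at -0.13 and Cald1 at 0.08. In the interaction, Cald1 was at -0.37, Egln1 at 0.02 and Junb at 0.46. Of these, Col1a1, Cebpb, Cald1 in the interaction and Junb passed the threshold in the new direction. The trends it removes are its only difference from the fit as reported.

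An estimated correlation ended 48 of the list calls. Among 273 list tests, the correction for length and GC content ended 5 and brought 9, RLE scaling ended 1 and brought 1, and the directional test of fry, which sets a list against no change instead of against the other genes, brought 165. Of the 234 list tests without HET replicate 2 or WT replicate 3, 3 lost and 5 gained a call. With groups at 0 set at their bound, 8 of 234 list medians of the pairwise comparisons moved (the interaction was not included), by at most 1.03 (actin isoform genes in WT over time, 2.14 to 1.11); the median of imprinted genes in KO against WT at day 4 went from -2.61 to -2.04. Depth limits the folds of genes with few counts in a group, whose SE is then set mainly by counting error.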

Other observations

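Only the comparison of escape genes with the other X genes was chosen after the result was seen; single genes come from the naming rule, except for the genes of the X chromosome test and the Y-linked genes. The BMP and TGF-beta list was called in no comparison, and its members Grem1, Bmp4 and Inhba went in different directions. Grem1, a BMP antagonist, stood at 2531 ± 25.3 CPM in WT at day 4 and at 88.1 ± 2.14 in KO, a log2 change of -4.85 ± 0.05, and fell in WT by 3.27 ± 0.05 from day 4 to day 14. Bmp4, a ligand that promotes bone formation, rose in WT by 3.32 ± 0.12 and was lower in KO than in WT at day 14 by -3.28 ± 0.13. Inhba, a subunit of activin, fell in WT by 4.55 ± 0.10. The largest edgeR adjusted p of these changes was 8e-12. Smarca2, an ATPase of the BAF complex, was higher in KO than in WT at day 4 by 2.40 ± 0.07 and at day 14 by 1.20 ± 0.07. Map2, a microtubule protein of neurons, was at 0.527 ± 0.162 CPM in WT and 42.3 ± 2.3 in KO at day 4, and Klf4, a factor used in reprogramming, was higher at day 14 in KO by 2.07 ± 0.11 and in HET by 1.95 ± 0.11. Ctsk, the collagen-degrading protease of osteoclasts, was higher in HET than in WT by 3.91 ± 0.21.

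Xist was high in HET and near 0 in WT and KO. An inactive X chromosome in the HET cells alone was tested on 5 genes that escape inactivation, whose median log2 changes were 0.40 over WT and 0.60 over KO, above the 0.3 written down beforehand. The other 480 tested genes of the X chromosome were higher in HET too, with medians of 0.19 and 0.32, and the escape genes did not separate from them (Wilcoxon's exact rank-sum test, p = 0.203 and 0.452). This later comparison leaves the explanation open, although the first criterion was met. Of the escape genes, Kdm6a was higher in HET than in WT by 0.99 ± 0.08, and Pbdc1 did not pass (edgeR adjusted p = 0.276). Against KO, Ddx3x went the other way, at -0.09, and did not pass (edgeR adjusted p = 0.216). These 3 genes are named here after their values were seen. The Y-linked genes Ddx3y and Eif2s3y had no count in any library, and Kdm5d and Uty had at most 2 counts over any group. Sex and the loss of a sex chromosome were not tested, and both stay open.

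Linked alleles carried with the targeted locus would concentrate changes near Actb if they altered mainly the genes of that region. Within 5 Mb of Actb, 3 of 122 genes (2.46%) differed between KO and WT by 2-fold or more with the same sign at both days. Elsewhere the share was 7.97% (Fisher's exact test p = 0.018, odds ratio 0.291), the opposite direction. Changes were thus not concentrated near the locus. Linked alleles that change genes elsewhere in the genome would leave no such concentration, so the test cannot exclude them.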
